A study of Halobacterium salinarum NRC-1 with 36 samples.

How the data were processed

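Halobacterium salinarum NRC-1 is an extremely salt-loving archaeon that can grow with or without oxygen. Per the labels, 1 fermentor culture was held at very low oxygen for 24 h and then brought quickly to high oxygen for 12 h. RNA was taken at 18 sampling times, at -5 and 0 min and then from 5 to 660 min. Each RNA was hybridised with a common reference RNA, taken from cells grown in mid-logarithmic phase, on a pair of two-colour arrays with the dyes exchanged. This gives 36 arrays. The labels name the dyes Alexa 547 and Alexa 647, and the array files call the first Alexa 546.

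The deposited array files hold spot intensity values on a linear scale, not background subtracted and not normalized, per the file headers. The scanner and its software are not given in the sources used here. The deposited value table of the same arrays holds log10 ratios. Its scale and direction were found by setting each column against that array's own intensities on spots at least 300 above background in both channels. All columns ran as Alexa 546 over Alexa 647, whichever dye held the sample, with correlations from 0.426 to 0.988 and slopes from 0.417 to 1.04. Column medians ran from -0.0909 to 0.221, and between 0% and 52.3% of a column's values were exactly 0. Whether and how the authors centred that deposited table, and what set values to 0, stays unknown. The column of 1 array, at 660 min with the sample in Alexa 547, matched another array better than its own.

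Each array had 10752 spots, 4 for each of 2688 probes. A gene symbol was given for 133 probes, none had several symbols, and 2555 were unnamed here. The symbols come from the platform annotation supplied with the series and can be old, and none of its gene identifiers matched the reference gene table of 2597 genes. Every gene-level statement therefore covers a small, fixed part of the genome. No column of another series was used.

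Analysis used R 4.3.3 and limma 3.58.1, with statmod 1.5.0. Spot means and background medians of the high scan were corrected with normexp (offset 50) and normalized within arrays by loess. Each ratio was turned to time sample over reference, the 4 spots of a probe were averaged, and the arrays of a time were averaged, since they share the same RNA extracts. This leaves 1 value per time and 18 values per probe. A loess fit centres each array, so a shift of all transcripts in one direction cannot be seen. It also removes any trend of the ratio with brightness, including a trend that belongs to the samples.

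Windows were fixed from the labelled times: baseline (-5 and 0 min), early (5 to 30 min, 4 times), middle (45 to 180 min, 5 times) and late (240 to 660 min, 7 times). The labels mark only the -5 min sample as low oxygen. The 0 min sample is labelled as the step from low to high oxygen and was counted with it, so every comparison with baseline rests on that choice. limma's lmFit and eBayes fitted all 18 times together and gave the differences between window means, with Benjamini-Hochberg adjustment over 2688 probes and a threshold of 0.05. A natural spline with 4 degrees of freedom over the rank order of times tested change at any time. No time had a second culture, so neighbouring times stand in for replicates and p-values measure the spread between these samples of 1 culture. Each probe has 1 estimate of that spread, shared by all windows. The samples at -5 and 0 min differed by a standard deviation of 0.477 across probes, more than any other neighbouring times. The shared estimate can therefore understate the uncertainty of the baseline, and adjusted p-values against baseline may be too small. No culture was kept without oxygen in parallel, and the labels give a rising cell density, so oxygen, elapsed time and growth cannot be told apart.

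Gene lists were fixed before the data were examined. The patterns of 9 of the 24 lists matched no symbol here, those of 6 matched 1 or 2, and 9 lists were tested with camera (correlation 0.01), with camera's estimated correlation and with fry. The fixed patterns missed some measured genes that belong with a list by function, among them infB (translation factors), rpmC (ribosomal proteins) and radB (DNA repair), so list counts cover matched symbols only. Values of rpmC and radB were added after they had been seen. Another 7 lists were written from the symbols on the array before any value of theirs was seen. Named genes follow a rule fixed before the data were examined. For early and late against baseline it takes up to 10 genes with a symbol each way, past the threshold and with every time of the window on the same side of both baseline values. For late against early it takes 5 each way, and for each fixed list up to 4 members with the largest difference. It also names arcA and citZ whatever their values. Other genes it lists have no named probe and were not analysed here.

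A probe counted as well above background where its mean intensity in the sample channel was over 1.5 times the local background mean. That ratio was chosen after the shares of bright probes, but no gene result, had been seen. A probe above it on no array of a window is called dim there and has only a bound. The bound, written as at least so many fold, comes from the sample channel's log2 values after loess and Aquantile normalization, with the lowest value of any well-above-background probe on the array in place of the dim probe's own where that was lower. The account of such a comparison gives no log2 difference. A probe dim in both windows gets no fold, and no bound is given where it would exceed the fold of the window means. The alternative without the 25% of probes of lowest mean intensity uses another criterion and keeps hisA, hisB and infB. Dyes were balanced in every window of the main fit. The runs without single arrays or without out-of-sequence arrays leave some times with 1 dye only and hold no dye term.

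The procedure was tested on simulated data with 50 probes at each fold, over 2688 probes. For early against baseline it recovered 64% of 1.5-fold and 92% of 2-fold changes. For middle against baseline the shares were 74% and 94%, for late against baseline 78% and 94%, and for late against early 84% and 98%. The spline recovered 48% of 1.5-fold and 92% of 2-fold changes. False calls were 7 of 185 early, 9 of 193 middle and 5 of 191 late against baseline. They were 9 of 200 late against early and 9 of 179 for the spline. Simulated noise was independent between times, and a change was constant within a window or, for the spline, a steady ramp. Serial dependence, trends inside windows and loss of signal near background were not simulated, so these shares need not hold for the real samples.

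Alternatives fixed in advance covered centring, background correction, scaling between arrays, the deposited value table, the 25% of probes of lowest mean intensity left out, each dye alone, array pairs kept separate, arrays numbered out of sequence, variance settings, window limits, spline settings and each time left out. Added after seeing the data were runs without the 660 min and the -5 min array in Alexa 547, 2 filters on probes above background, a term for the out-of-sequence arrays, list tests among named genes, and list tests without the out-of-sequence arrays. Arrays numbered 10682 or higher were counted as out of sequence. This takes in array 10682 at 660 min, which follows its partner, 10679, in ascending order and so need not belong with the others.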

Results

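Transcript levels of a Halobacterium salinarum NRC-1 culture were measured before and after a rapid shift from very low to high oxygen, at 18 times on 36 arrays. The baseline window held 2 times (4 arrays), the early window 4 times (8 arrays), the middle window 5 times (10 arrays) and the late window 7 times (14 arrays). The number of arrays limits the precision. Arrays of a time share RNA and were averaged, so the fit rests on 18 times of a single culture, 2 of them at baseline. The mean share of probes well above background in the sample channel was 37.9% at baseline, 47.7% early, 62.9% in the middle and 53.0% late. The background of that channel averaged 916 ± 297 (SD) intensity units at baseline, 695 ± 254 early, 291 ± 93.4 in the middle and 535 ± 533 late. Both measures therefore moved with the windows that every gene comparison uses. The dye-swapped arrays of a time correlated across probes with r from 0.288 to 0.778 (median 0.491). Among arrays of the same dye orientation the lowest correlation was -0.0631.

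**Figure D1:**
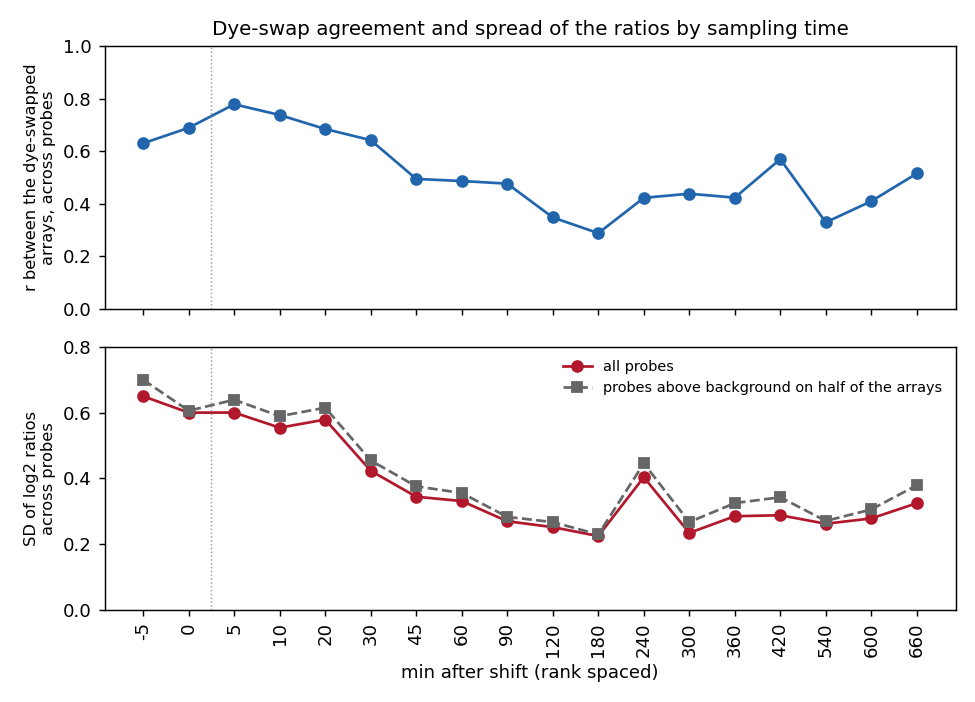
Correlation across probes between the dye-swapped arrays of each time (upper panel, r) and standard deviation of the log2 sample/reference ratios across probes (lower panel, log2 units), over sampling time in min, spaced by rank; the dotted line separates the baseline times. The correlation is highest at 5 min (0.778) and lowest at 180 min (0.288), and the standard deviation runs from 0.649 at -5 min to 0.224 at 180 min.

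The first question was which transcripts changed at any time. Transcripts of infB (translation initiation factor IF-2), pan1, serS (seryl-tRNA synthetase) and arcA (arginine deiminase, the entry enzyme of arginine fermentation) all changed over the course, with adjusted p of 5.46e-09, 3.51e-09, 4.45e-07 and 5e-05 in limma's spline test. The test passed 76 of the 133 named genes and 1678 of 2688 probes. The first principal component held 53.0% of the variance and ran from -18.9 at 5 min to 13.2 at 540 min.

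From 5 to 30 min after the shift, 6 named transcripts rose and 2 fell by the rule for named genes. The histidine synthesis genes hisA and hisB were not well above background at baseline and rose at least 1.24-fold (adjusted p = 0.0337) and at least 1.55-fold (adjusted p = 0.00215). The level of serS rose 1.54-fold (log2 difference 0.62 ± 0.12, SE, adjusted p = 0.00399). Transcripts of glyA (serine hydroxymethyltransferase) rose 1.5-fold (0.59 ± 0.13, adjusted p = 0.00843) and those of cheY, the response regulator of chemotaxis, 1.48-fold (0.57 ± 0.12, adjusted p = 0.0073). The infB probe, also dim at baseline, passed upward (adjusted p = 0.0257) with a lower bound of 1.00-fold. Transcripts of cobN, a subunit of the cobalt chelatase of vitamin B12 synthesis, fell (-0.56 ± 0.12, adjusted p = 0.00838), and the mamA probe passed downward (adjusted p = 0.0406) while dim in the early window, so no fold is given.

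Among the fixed lists, the 4 measured cobalamin (vitamin B12) synthesis genes shifted down early, with 1 fall and 3 falls adjusted over the list alone. Their median difference was -0.42, and the camera adjusted p was 0.01, with adjusted p = 0.415 with an estimated correlation and 0.00701 by fry. The camera call was also lost under median centring (median -0.28, adjusted p = 0.409) and without the 0 min sample, where the median stayed at -0.42 (adjusted p = 0.225). Early against baseline 7.6% of all probes and 6.8% of named genes passed. In the aminoacyl-tRNA synthetase list serS alone of 12 passed, in the flagellin and chemotaxis list cheY alone of 4, both also when adjusted over the list alone. No member of the retinal protein, tricarboxylic acid cycle, chaperone, DNA replication, DNA repair or purine and pyrimidine lists passed, over all probes or adjusted over the list alone, and none of these lists passed camera. By fry the DNA replication list passed downward (adjusted p = 0.0227), but not by camera with an estimated correlation (adjusted p = 0.415). The differences of arcA (-0.14 ± 0.13, adjusted p = 0.573) and of citZ, citrate synthase (-0.05 ± 0.10, adjusted p = 0.83), did not pass.

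For early against baseline limma passed 203 of 2688 probes, 145 up and 58 down. Of these, 13 rose and 1 fell by at least 1 log2 unit, and 7 of the named genes rose and 2 fell. Scaling between arrays left 6 probes (6 up, 0 down), the value table gave 14 (14 up, 0 down), leaving out 20 min 121, leaving out 10 min 122 and leaving out 0 min 409 (179 up, 230 down). All 8 genes named by the rule in this comparison lost their call under scaling and under the value table, where the differences of glyA (0.69) and cheY (0.72) were larger, and 7 of them with the sample in Alexa 647 alone, while over all alternatives the mamA call was lost in 18 of 32 (in 5 of them with an unchanged difference and adjusted p from 0.0506 to 0.0564), infB in 12 of 34 (adjusted p = 0.0651 with time as a random block and an unchanged difference, and 0.452 without the -5 min array in Alexa 547), hisA in 11 of 34 and glyA in 5 of 35 (0.33, adjusted p = 0.119, without 0 min).

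From 45 to 180 min, transcripts of infB, dim at baseline, rose at least 1.74-fold (adjusted p = 8.53e-06), those of serS rose by 1.07 ± 0.12 log2 units (adjusted p = 8.53e-06), and pan1 fell by 1.43 (SE 0.26, adjusted p = 0.000623). These were the 3 named genes past 1 log2 unit, and they were chosen here after their values were seen, as were the values of the arginine fermentation genes. Transcripts of arcA fell by 0.57 (SE 0.13, adjusted p = 0.00254), and arcC lay 0.41 below baseline (SE 0.16, adjusted p = 0.0517). limma passed 864 probes, 442 up and 422 down, with 25 named genes up and 19 down. With the 25% of probes of lowest mean intensity left out, 422 rose and 257 fell. The count ranged widely with the processing, from 186 under scaling between arrays to 1454 in the value table, of which 474 were shared with the main fit. The arcA call was lost under median centring (-0.04) and scaling (-0.31) and turned to 0.41 in the value table (adjusted p = 0.0487), the pan1 call was lost under scaling (-0.40), and arcC passed in 13 of 34 alternatives.

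By the late window, the transcript of rpl12p, a protein of the ribosomal stalk, rose 2.55-fold (1.35 ± 0.20, adjusted p = 2.71e-05), and infB at least 2.95-fold (adjusted p = 3.26e-08). The levels of serS and lysS, seryl- and lysyl-tRNA synthetases, rose 2.01-fold (1.01 ± 0.11, adjusted p = 1.03e-06) and 1.77-fold (0.82 ± 0.12, adjusted p = 2.11e-05). Both subunits of succinyl-CoA synthetase rose, sucD 1.84-fold (0.88 ± 0.14, adjusted p = 3.69e-05) and sucC 1.83-fold (0.88 ± 0.15, adjusted p = 0.00011). The others among the 10 largest rises were hisF of histidine synthesis (1.76-fold, above background on 1 of 4 baseline arrays), phoU of phosphate regulation (1.80-fold), thiL, thiamine monophosphate kinase, dim at baseline (at least 1.26-fold), and nadC of NAD synthesis, which passed (adjusted p = 0.000789) but was not well above background in either window. The nadC call was lost under median centring (adjusted p = 0.0725), and its sign turned in the value table. The phoU call was lost in 7 of 35 alternatives, among them scaling (0.39) and no background correction (0.44). Leaving out the -5 min array in Alexa 547 alone took phoU from 0.85 to 0.45 (adjusted p = 0.206). That run leaves -5 min with the sample in Alexa 647 only, so the array and the dye cannot be told apart. With the sample in Alexa 647 alone at all times the difference of phoU was 0.31.

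**Figure D2:**
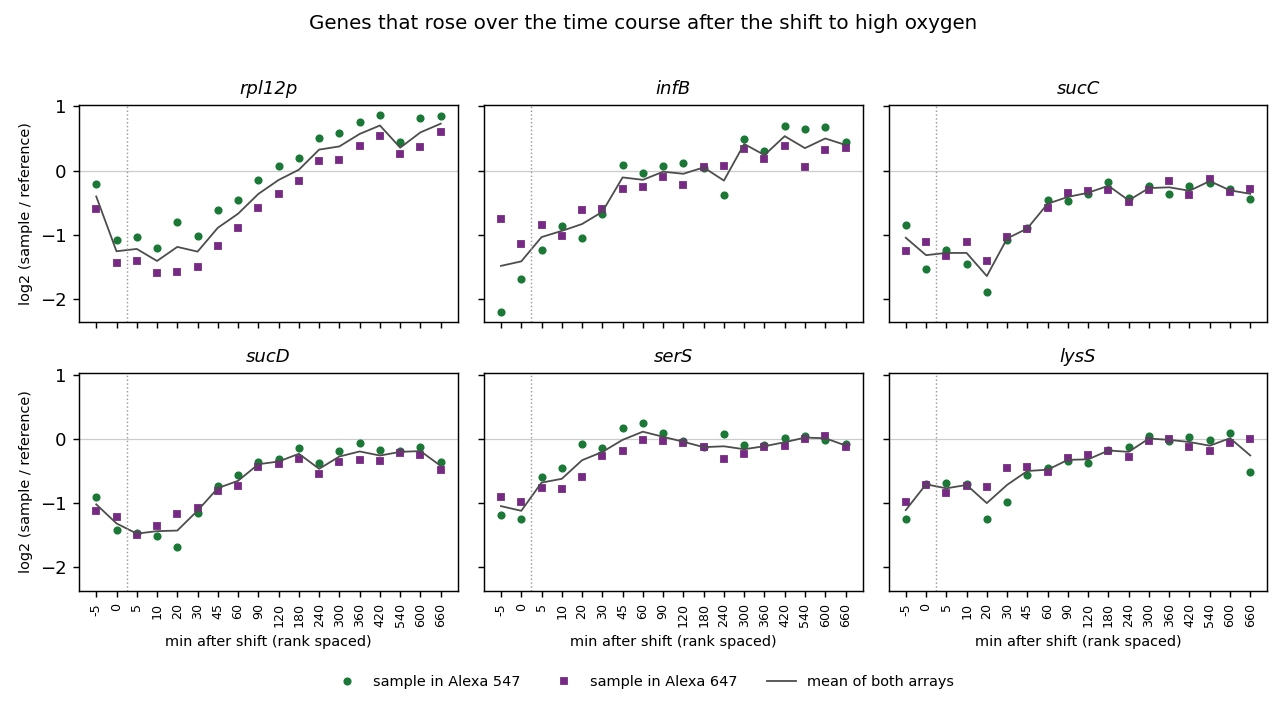
Log2 sample/reference ratio of 6 genes that rose, over sampling time in min spaced by rank, with points for each array by dye of the sample and a line for the mean of both arrays; the dotted line separates the baseline times. The mean of rpl12p runs from -1.26 at 0 min to 0.73 at 660 min. The infB probe was dim at baseline.

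Transcripts of pan1 fell (adjusted p = 1.03e-06), but its probe was well above background on 1 of the 14 late arrays, so the size of the fall is not given. The cobalamin genes cbiG and cbiQ fell 2.55-fold (-1.35 ± 0.13, adjusted p = 2.67e-07) and 2.36-fold (-1.24 ± 0.15, adjusted p = 2.61e-06), and thiD and thiC, which make the pyrimidine part of thiamine, fell 2.46-fold and 2.37-fold. The transcript of dpsA, an iron-storing protein that protects DNA, fell 2.35-fold (-1.23 ± 0.16, adjusted p = 6.06e-06). Transcripts of carA, a subunit of carbamoyl phosphate synthase, fell 1.95-fold, and the mamA probe passed downward (adjusted p = 3.19e-05) while dim in the late window, so no fold is given. In the value table cbiG (-0.16), cbiQ (-0.12), thiD (-0.13), thiC (-0.0005), dpsA (-0.03) and carA (-0.10) lost their call, with adjusted p from 0.34 to 0.999. The hutG probe of histidine breakdown passed (adjusted p = 4.15e-05) while dim in both windows. The probe of csg, the surface-layer glycoprotein, passed in the downward direction (adjusted p = 1.77e-05) but was saturated on every array of both windows, so no fold is given. The csg call was lost under median centring (adjusted p = 0.98) and turned upward in the value table (adjusted p = 0.046). Because of the saturation, neither direction is relied on.

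**Figure D3:**
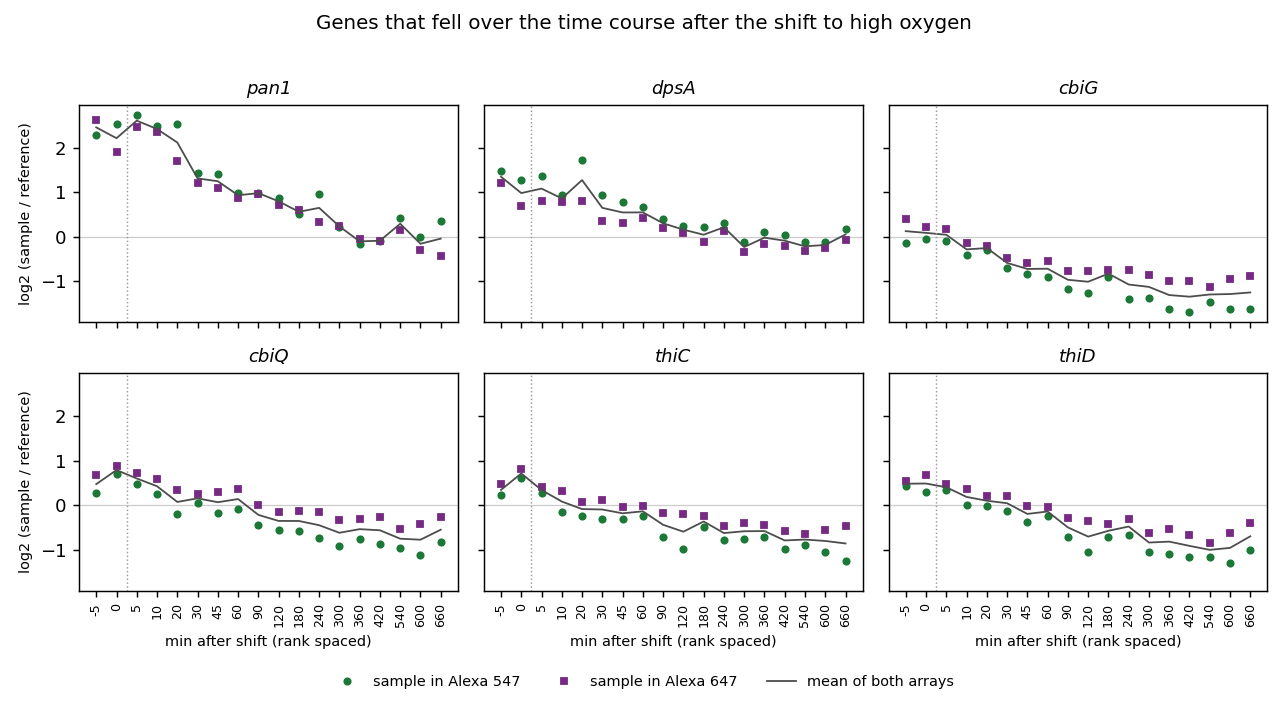
Log2 sample/reference ratio of 6 genes that fell, over sampling time in min spaced by rank, with points for each array by dye of the sample and a line for the mean of both arrays; the dotted line separates the baseline times. The mean of cbiG runs from 0.09 at 0 min to -1.25 at 660 min. The pan1 probe was well above background on 1 of the 14 late arrays, and in the value table the other 5 genes lost their call late against baseline.

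All 4 measured cobalamin synthesis genes fell late, over all probes and adjusted over the list alone, with a median of -1.01. The camera adjusted p was 0.00316, with adjusted p = 0.278 with an estimated correlation and 4.33e-07 by fry, and it was lost under median centring (median -0.43, adjusted p = 0.221). Transcripts of cobN (-0.78) and cbiT (-0.69) completed the list, and both lost their call under median centring (adjusted p = 0.0595 and 0.246) and lay above baseline in the value table. Late against baseline 48.8% of all probes and 49.6% of named genes passed, so list counts near that share do not set a list apart. Of 12 aminoacyl-tRNA synthetases 5 rose (serS, lysS, glyS 0.58, hisS and proS) and aspS fell (-0.38), with the same counts adjusted over the list alone, and the list did not pass camera (median 0.26, adjusted p = 0.0657). It passed under median centring (median 0.36, adjusted p = 0.0125) and without the 0 min sample (median 0.43, adjusted p = 0.0124). The calls of glyS, above background on 1 of 4 baseline arrays, and hisS, dim at baseline, were lost in the value table (0.002 for glyS) and with the sample in Alexa 647 alone, among other alternatives. Of 5 retinal proteins and transducers 3 fell, namely the chloride pump halorhodopsin (hop, -0.83), the transducer htr1 (-0.52) and sensory rhodopsin I (sop1, -0.44). Adjusted over the list alone 4 fell, and the list did not pass camera (adjusted p = 0.0657). In the value table htr1 (-0.10) and sop1 (-0.05) lost their call, and sop1 also did under median centring (-0.27). The sop1 call was lost in 6 of 35 alternatives, among them Alexa 547 alone (-0.39) and without -5 min (-0.32).

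The tricarboxylic acid cycle list had 2 rises (sucC, sucD) and 1 fall of 4, also adjusted over the list alone, and passed camera only under median centring (median 0.90 against 0.47, adjusted p = 0.0271). The fall was that of icd, isocitrate dehydrogenase (-0.25 ± 0.10, adjusted p = 0.0426), and it turned to a rise of 0.49 under median centring (adjusted p = 0.00218) and of 0.90 in the value table (adjusted p = 0.000174). Besides these reversals the icd call was lost in 13 of 35 alternatives. Among them were scaling (-0.18) and Alexa 647 alone (-0.15), and the run without 90 min, where the difference stayed at -0.25 (adjusted p = 0.0526). The difference of citZ was 0.07 ± 0.10 (adjusted p = 0.543). In the chaperone and proteasome list dnaK (0.76) and panB (dim at baseline) rose and pan1 fell, of 6, also adjusted over the list alone. Its median (0.10) and mean (-0.10) differed in sign. Under scaling dnaK (0.30) and panB lost their call, and panB, caught by the list's pattern, usually denotes a pantothenate synthesis gene. Of 10 purine and pyrimidine genes guaB (0.70) and pyrF (0.59, above background on 1 of 4 baseline arrays) rose and purE (-0.83), pyrB (-0.74) and pyrI (-0.44) fell, also adjusted over the list alone, and pyrB lay above baseline under median centring and in the value table, where purE (-0.16) lost its call. In the DNA replication list orc8 (0.40) rose and orc7 (-0.38) and gyrA (-0.38) fell, of 4, also adjusted over the list alone, but the gyrA call was lost in 22 of 35 alternatives and its sign turned in the value table. In 9 of these losses, each without 1 time of another window, the difference stayed at -0.38 with adjusted p from 0.0512 to 0.0554, while it was -0.04 under median centring. The orc7 call was lost in 5 alternatives, among them scaling (-0.08), and the orc8 call in 3. Apart from the cobalamin list, no fixed list passed camera late against baseline. By fry the tricarboxylic acid cycle (adjusted p = 0.000968), aminoacyl-tRNA synthetase (0.000364) and retinal protein lists (0.000203) passed as well. With camera's estimated correlation none of these did (adjusted p = 0.604, 0.411 and 0.411).

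None of 3 DNA repair or 4 chemotaxis genes in the lists passed, over all probes or adjusted over the list alone. The recombinase gene radB, missed by the repair list's pattern and above background on 1 of 4 baseline arrays, passed downward (-0.38 ± 0.14, adjusted p = 0.0348), a call lost in 8 of 34 alternatives, among them scaling (-0.19) and without -5 min (-0.11). The repair gene mutL lay 0.49 above baseline without the arrays numbered out of sequence (adjusted p = 0.0112), and cheB 0.86 above it in the value table (adjusted p = 0.00629). Small lists gave dpsA as the fall of 2 oxidative stress genes (msrA -0.23, adjusted p = 0.101), and rpl12p and phoU, both up, as the single genes matched by the ribosomal protein and phosphate uptake patterns. Another ribosomal protein gene, rpmC, missed by its pattern, did not pass (0.23, adjusted p = 0.647). In the respiratory chain list nuoL (-0.05) and sdhC (0.09) did not pass, nor did arcA (-0.26 ± 0.12, adjusted p = 0.081) and arcC (0.18) of arginine fermentation or bat (dim at baseline), the activator of bacteriorhodopsin synthesis. These counts also held adjusted over the list alone. The difference of arcA turned to 0.38 under median centring (adjusted p = 0.0292) and 0.78 in the value table (adjusted p = 0.000958), and that of nuoL to 0.54 (adjusted p = 0.00256) and 0.89 (adjusted p = 0.00125).

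**Figure D4:**
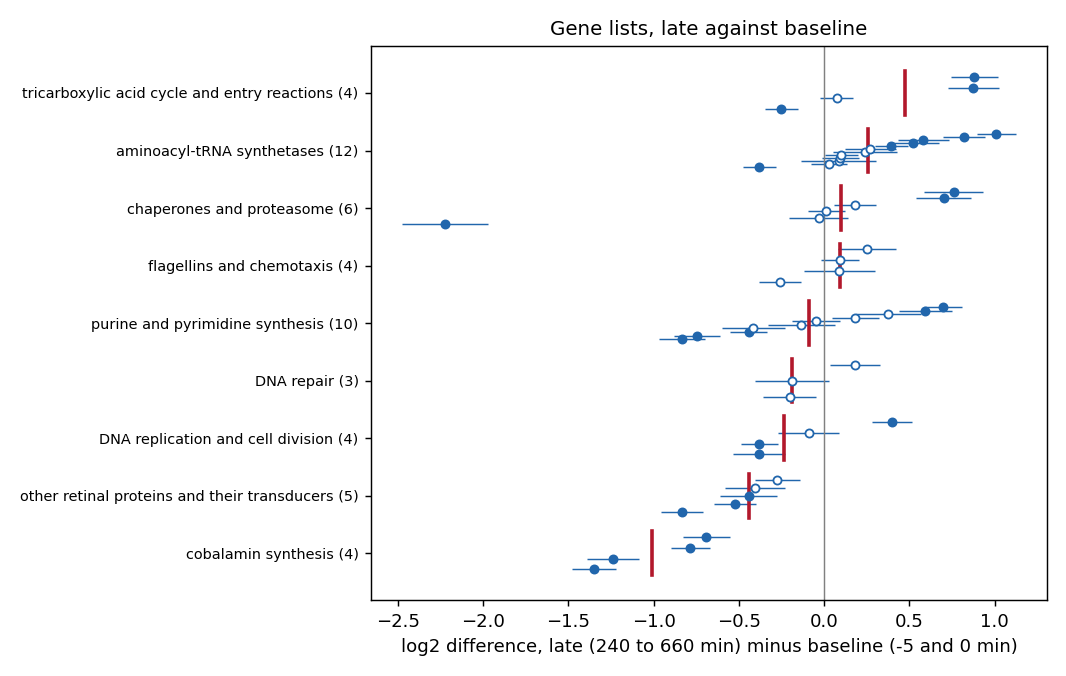
Log2 difference of late minus baseline for each member of the 9 tested lists, with its standard error from limma (horizontal bars), filled where the adjusted p was under 0.05; red lines are list medians and numbers of members stand in parentheses. The 4 cobalamin genes lie below 0, with a median of -1.01; under the value table cobN and cbiT lay above 0.

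For late against baseline limma passed 1311 of 2688 probes, 637 up and 674 down, of which 111 rose and 110 fell by at least 1 log2 unit. Named genes counted 34 up and 32 down. Among unnamed probes the furthest were those first spotted at positions 1547 (2.32) and 2371 (2.13) upward and 4103 (-2.82) and 5021 (-2.70) downward. Scaling between arrays left 824 probes. The value table gave 1455, of which 692 were shared with the main fit. A filter to the 1470 probes above background on at least 50% of all arrays left 842, with fewer probes tested, and one requiring this in every window left 603 of 1031.

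Late against early compares windows that both lie after the shift. The transcripts of rpl12p (1.79 ± 0.16, adjusted p = 4.93e-08), infB (1.19 ± 0.11, adjusted p = 6.51e-08), sucD (1.08 ± 0.11, adjusted p = 1.4e-07) and sucC (1.01 ± 0.12, adjusted p = 9.05e-07) rose, and nadC passed while dim in both windows. Transcripts of pan1 (adjusted p = 1.23e-07, its late level near background), dpsA (-1.03 ± 0.13, adjusted p = 1.75e-06), thiD (-1.0 ± 0.12, adjusted p = 9.05e-07), cbiG (-0.97 ± 0.10, adjusted p = 2.33e-07) and cbiQ (-0.92 ± 0.12, adjusted p = 2.9e-06) fell, and all of these but pan1 lost their call in the value table (adjusted p from 0.32 to 0.695). Here 56.2% of all probes and 51.9% of named genes passed. In the lists, 5 of 12 aminoacyl-tRNA synthetases rose and 0 fell, 3 of 5 retinal proteins and transducers fell, and 3 of 4 cobalamin genes fell (4 adjusted over the list alone). The bat probe, above background on 1 array of each window, passed downward (adjusted p = 0.0181). Of 4 tricarboxylic acid cycle genes 2 rose, of 4 chemotaxis genes 1 rose and 2 fell, of 6 chaperone and proteasome genes 2 rose and 1 fell, of 10 purine and pyrimidine genes 3 rose and 3 fell, and of 4 DNA replication genes 1 rose. None of 3 DNA repair genes passed. The counts adjusted over the list alone were the same for all these lists but the cobalamin list. No fixed list passed camera here, the lowest adjusted p being 0.0891, but the tricarboxylic acid cycle and aminoacyl-tRNA synthetase lists passed under median centring (both adjusted p = 0.0124), with medians of 0.90 against 0.56 and 0.28 against 0.20. Without 20 min the retinal protein and cobalamin lists passed (both adjusted p = 0.0445), with medians of -0.72 against -0.53 and -0.64 against -0.57. By fry the tricarboxylic acid cycle (adjusted p = 4.69e-06), cobalamin (1.13e-05), retinal protein (3.94e-05) and aminoacyl-tRNA synthetase lists (0.000262) passed late against early. With camera's estimated correlation none of these did (adjusted p = 0.407 for each).

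limma passed 1510 probes for late against early, 699 up and 811 down, with 39 named genes up and 30 down. The value table gave 1633, of which 858 were shared with the main fit. With the 25% of probes of lowest mean intensity left out the count was 633 up and 534 down of 2016. The filters on probes above background left 927 of 1470 and 670 of 1031.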

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

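The tests of spread among bright probes, both tests on the -5 and 0 min samples and both tests on the 240 min sample were chosen after the results were seen, and their bounds with standard errors were set then too. The splits that include the baseline were added after the counts they test had been seen. Earlier versions on a stricter set of 1031 probes were also run and are given in the other observations.

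Of 177 sets of values, 1 for each of the early, middle and late windows of 59 named genes (the baseline has too few times for the test), 14 held 1 sampling time far from the others by Dixon's test, where chance gives about 1 in 20. In the early window these were cheY (-0.174 at 30 min), icd (-0.115 at 30 min), sucD (-1.12 at 30 min), psmB (0.322 at 20 min) and sop1 (-0.253 at 20 min), as log2 ratios to the reference. In the middle window they were hisB (-0.511 at 45 min), mamA (0.531 at 60 min) and glyA (-0.845 at 180 min). In the late window they were gyrB (-0.911) and infB (-0.156) at 240 min, and hisS (-0.136), nuoL (-0.242), panB (0.220) and pyrF (0.0449) at 660 min. The rate of 1 in 20 holds only for values without a trend. Many of these genes were named because they changed, and a trend can set the first or last time of a window apart. The flags at 30, 45, 180, 240 and 660 min lie at such times, while those at 20 and 60 min do not. The number of flags therefore does not show that samples were aberrant. No named gene had opposite calls early and late against baseline.

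The spread of log2 ratios across probes fell over the time course, from a median standard deviation of 0.589 at baseline and early times to 0.285 late. Among probes above background on at least 50% of all arrays, the spread shared by both dye orientations was still 0.525 times as large late as before (SE 0.0498), which argues against noise near background as the whole cause. Within the arrays of a time, spread went with sample background with r = 0.445 (permutation p = 0.062, adjusted 0.093 over 3 relations; rho = 0.368, p = 0.134, adjusted 0.201; 18 times), and r was 0.705 without the 2 farthest times, so a part played by background stays open. No biological explanation, such as an approach of the culture to the state of the reference cells, was tested.

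The samples at -5 and 0 min differed by a standard deviation of 0.477 across probes, more than any other neighbouring times. This difference correlated across probes between the dye orientations with r = 0.489, which argues against the single out-of-sequence array at -5 min as the whole cause, though probes are not independent replicates. The difference between 0 and -5 min had r = -0.00553 (SE 0.0261) with late minus early, so a start of the response at 0 min stays open. Among named genes chosen after their values were seen, trpC differed by 1.29 and mutL by 1.16, both more in Alexa 547 (1.92 and 1.94) than in Alexa 647 (0.656 and 0.384).

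The 240 min sample stood apart, with standard deviations of 0.379 from 180 min and 0.370 to 300 min, and those differences correlated between dyes with r = 0.579 and 0.721 across probes. Out-of-sequence arrays minus their partners at 4 other times followed the 240 min deviation with a mean r of 0.0708 (SE 0.0744), against -0.224 to 0.311 in 13 in-sequence pairs, so a batch shared by those arrays cannot be told apart from other causes. The r was 0.225 at -5 min, 0.0421 at 300 min, -0.122 at 420 min and 0.138 at 660 min. The 660 min array is numbered in ascending order after its partner and may not belong in this group. A partial return of the low oxygen profile also stays open (r = 0.0726, SE 0.0261). Named genes farthest from their neighbours, chosen after their values were seen, were rpmC (-1.30), folP (-0.94), phoU (-0.86), truA (-0.81), hisG (0.81) and cheA (-0.79).

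For late against early, 1 of 100 drawn splits of the 11 times, the real one, gave as many probes (1510), and the highest other gave 837. That split put 5, 10, 20 and 240 min together. For change over the course, 1 of 100 orders of the 18 times, the real one, gave as many (1678), the highest other 612. Shuffling treats times as exchangeable, which a single culture followed over time does not make them. Windows are blocks of neighbouring times, so any steady drift of the culture would put the real grouping first. The splits and orders show only that the counts depend on the order of the times, and they cannot tell a response from drift. For late against baseline, 1 of the 36 splits of 9 times, the real one, gave as many probes (1311), the highest other 159 (-5 and 240 min as baseline). For middle against baseline, 1 of 21 splits of 7 times did (864), the highest other giving 1. The same limit holds for both. For early against baseline the 15 splits are too few for a share under 0.05, with 203 probes in the real one and 124 in the highest other.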

How the results depend on the processing

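Runs without the 660 min or the -5 min array in Alexa 547, both filters on probes above background, the term for out-of-sequence arrays, list tests among named genes and list tests without out-of-sequence arrays were chosen after seeing the data. Of the filters, the one on every window was tried first and then replaced by that on all arrays. An uncalled value that changed sign within 1 standard error counts as unchanged. Where no cause is named below, the cause was not tested. Signal over background and the single culture limit all comparisons. Where leaving out a time left 1 baseline sample, that sample was assumed to vary like the others.

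Under all alternatives together, values of named genes were unchanged in 2537 cases, lost their call in 161, gained one in 52 and reversed in 44. The unchanged cases do not measure robustness, since leaving out a time of another window can change only the adjusted p and not the difference. The baseline of -5 min alone and the run without 0 min are the same fit, so counts over alternatives hold it more than once. Of 81 gene results, 20 had no change under any alternative, among them infB, rpl12p, serS, sucC, sucD and pan1 late against baseline. Other gene calls in the text, among them those of proS, aspS and pyrI late against baseline, were not run under the alternatives. All 10 genes of late against early kept their call under every alternative that tested them but the value table, where dpsA, thiD, cbiG and cbiQ lost it and nadC reversed (-0.0411). Of 56 gene results late against baseline, the value table ended 13 calls and reversed 12 values, median centring 8 and 5, and scaling 8 and 5. The value table moved the median of all probes by -0.113 for middle against baseline, and leaving out the 25% of probes of lowest mean intensity moved it by 0.104 there and 0.123 for late against baseline.

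For early against baseline the count of 203 fell to 97 without background correction, 6 under scaling (6 up, 0 down) and 14 in the value table (14 up, 0 down), and was 409 with -5 min alone as baseline (123 shared). Leaving out each time gave 121 (without 20 min) to 409 (without 0 min), with 122 without 10 min. For middle against baseline the count of 864 became 1359 under median centring, 506 without background correction, 186 under scaling, 1454 in the value table and 571 in Alexa 547 alone. For late against baseline 1311 became 824 under scaling (780 shared). The value table gave 1455 late against baseline, sharing 692 of the 1311, and 1633 late against early, sharing 858 of 1510. For middle against baseline it shared 474 of the 864. Median centring gave 1623 late against baseline (981 shared) and 1573 late against early (1151 shared). Counts of like size therefore need not hold the same probes.

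With the filter on all arrays (1470 probes tested), 1032 probes changed over the course, 842 late against baseline and 927 late against early. With the filter on every window (1031 tested) the counts were 737 over the course, 88 early, 408 middle and 603 late against baseline, and 670 late against early. Fewer probes were tested in both. With the 25% of probes of lowest mean intensity left out (2016 tested) the counts up and down were 152 and 43 early, 422 and 257 middle and 604 and 418 late against baseline, and 633 and 534 late against early. With a term for out-of-sequence arrays the counts were 1722, 240, 904, 1326 and 1483, and without those arrays 1718, 165, 802, 1254 and 1423, in the same order. The out-of-sequence arrays hold no early or middle time and only -5 min at baseline, and they were not fitted alone. Leaving out each time gave 1494 to 1810 over the course, 723 to 904 middle against baseline, 996 to 1355 late against baseline and 1319 to 1608 late against early.

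Of 27 tests of fixed lists 2 passed camera, against 0 with an estimated correlation, 10 with fry, 4 under median centring (0 shared), 2 among named genes, 2 without out-of-sequence arrays and 2 to 4 without single times (4 without 20 min). The median correlation of dye-swapped arrays, 0.491, was 0.316 under median centring, 0.581 without background correction and 0.571 in the value table.

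Early against baseline, arcA was 0.0362 under median centring and 0.159 in the value table, and citZ 0.100005, 0.145 and, in Alexa 547 alone, 0.0732. Middle against baseline, arcA was 0.413 in the value table. Late against baseline, the value table gave reversed values for nadC (-0.120), csg (0.774), arcA (0.778), sop2 (0.409), nuoL (0.890), icd (0.901), gyrA (0.281), uvrA (0.224), cheB (0.859), pyrB (0.475), cobN (0.145) and cbiT (0.108). Median centring did so for arcA (0.379), nuoL (0.541), icd (0.486), cheB (0.371) and pyrB (0.0363). Scaling did so for arcA (0.0695), sdhC (-0.0839), cheR (-0.0637), cheY (-0.165) and cheA (-0.215). In Alexa 547 alone gyrB was 0.432, and in Alexa 647 alone sdhC was -0.123, mutL 0.475 and rpmC -0.257. With -5 min alone as baseline psmB was -0.0236 and uvrA 0.0565. Without out-of-sequence arrays mutL was 0.487 and uvrB -0.115, and without the -5 min array in Alexa 547 they were 0.393 and -0.0969. Leaving out each time gave ranges of -0.0236 to 0.387 for psmB, -0.458 to 0.0565 for uvrA, -0.768 to 0.393 for mutL, -0.180 to 0.543 for uvrB and -0.133 to 0.313 for cheA.

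List medians reversed under median centring for early against baseline in the tricarboxylic acid cycle (0.0280) and purine and pyrimidine lists (0.0504), for late against baseline in DNA replication (0.0196) and protein export (0.557), and for late against early in DNA replication (0.111), chemotaxis (0.201) and central carbon (0.209). Without out-of-sequence arrays central carbon early was -0.186. Leaving out each time gave, early against baseline, -0.0681 to 0.165 for retinal proteins, -0.130 to 0.209 for aminoacyl-tRNA synthetases, -0.174 to 0.0316 for chaperones, -0.188 to 0.0698 for central carbon and -0.283 to 0.159 for protein export. Late against baseline it gave -0.203 to 0.0565 for DNA repair and -0.0281 to 0.199 for chemotaxis, and late against early -0.0989 to 0.0414 for DNA replication.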

Other observations

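The earlier versions of tests given here and the lists written from the symbols on the array were not among the choices fixed before the data were examined. Histidine synthesis genes rose early against baseline in 2 of 6 cases (hisA and hisB), also adjusted over the list alone, with a camera adjusted p of 0.0444 and adjusted p = 0.0994 with an estimated correlation. That camera call was also lost without the out-of-sequence arrays (adjusted p = 0.142) and without -5 min (0.201), 0 min (0.160), 5 min (0.0945) or 180 min (0.0512), while the list's median of 0.284 became 0.311, 0.348, 0.470 and 0.378 and was unchanged without 180 min. Late against baseline 3 of 6 rose (hisF, hisB and hisI, the last by 0.47), and the camera adjusted p was 0.286. Of 3 histidine breakdown genes 2 passed downward late, all dim. Of 7 genes of nitrogen and carbamoyl phosphate assimilation, the glutamate dehydrogenases gdhA1 (0.65) and gdhA2 (0.42) rose late, and carA, carB (-0.69) and glnA, glutamine synthetase (-0.56), fell. The late values of hisB, hisI, gdhA1, gdhA2, carB and glnA were not run under the alternatives. In the value table carA lost its call (-0.10, limma adjusted p = 0.64).

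Of 5 genes of thiamine and molybdenum cofactor synthesis 1 rose (thiL) and 2 fell late, with a median of 0.01 and a mean of -0.34. Of 7 taxis transducers 3 passed downward late (htr1, htr6 -0.43 and htr18, dim), and 2 adjusted over the list alone. Of 7 central carbon genes outside the fixed list eno, enolase (0.55), rose and ppsA, phosphoenolpyruvate synthase (-0.67), fell. Of 3 protein export genes srp19 (dim at baseline) rose and secF (-0.30) fell, while the list's median (-0.10) and mean (0.03) differed in sign. Of the genes named in this paragraph so far, only thiL and htr1 were run under the alternatives. Apart from that early call of histidine synthesis, none of these lists passed camera in any of 3 comparisons. Histidine breakdown early against baseline (median -0.401, adjusted p = 0.0619) passed under median centring (-0.489, adjusted p = 0.0241) and without 10 min (-0.471, adjusted p = 0.0202).

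On the stricter set of 1031 probes the shared spread late over baseline and early was 0.549, the -5 minus 0 min difference correlated between dyes with r = 0.588, and 0 minus -5 min had r = -0.00583 with late minus early. The -5 minus 0 min difference also had r = 0.294 (Alexa 547) and 0.234 (Alexa 647) with the 240 min deviation, a difference of 0.06. These correlations are across probes, which are not independent replicates.

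Before loess, log2 ratios sloped with brightness, on average by -0.261 at baseline, -0.200 early, -0.0898 in the middle and -0.0454 late. Loess removed this trend from the main values, and median centring left it in. Whether it accounts for the values that reversed under median centring was not tested. Over the 18 times the slopes in Alexa 547 and Alexa 647 correlated with r = 0.871 (permutation p = 1e-05, the smallest these permutations can give, adjusted 3e-05 over 3 relations; rho = 0.814, p = 0.00012, adjusted 0.00036), and r was 0.901 without the 2 farthest times. Slope against sample background within the arrays of a time gave r = -0.0415 (permutation p = 0.871; rho = -0.0671, p = 0.79; r = -0.170 without the 2 farthest times).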
